A study of Nothobranchius furzeri with 42 samples.

How the data were processed

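RNA was sequenced from 5 tissues of female African turquoise killifish (Nothobranchius furzeri, the short-lived GRZ strain), some kept in water with alendronate and some with distilled water as placebo. Alendronate is a nitrogen-containing bisphosphonate, a class of drugs that binds bone mineral and inhibits farnesyl diphosphate synthase, mainly in bone-resorbing osteoclasts. Each of the 42 libraries was assigned to its tissue and arm from its labels. The title of a library carries a prefix of a letter and a number, read here as 1 fish. There are 9 prefixes, 5 with alendronate and 4 with placebo, and fish are named below by arm and number. How many tanks held the fish is not given in the sources used here, so p-values measure the spread between fish and cannot separate treatment from tank. The serial numbers of all alendronate libraries precede those of all placebo libraries, so treatment cannot be separated from this order either.

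The authors deposited a single table of whole-number read counts per Ensembl gene ID, with one column per library and no normalization, for 25475 genes. The submitters' processing notes name CASAVA, bcl2fastq, FastQC 0.12.1, MultiQC 1.28, Trim Galore 0.6.10, STAR 2.7.10b and SAMtools 1.13, without a role or an order. The program that counted reads, its strand setting, the genome build and the annotation release are not given in the sources used here. Without the strand setting, overlapping and antisense genes cannot be told apart. How reads that match several near-identical gene copies were counted is not given either, so counts of such copies are uncertain too. The table holds 0 rows that name no gene, and 0 of its columns belong to no sample. Total counts ran from 20485992 to 35717250 per library.

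The files do not pair gene IDs with names. The gene table at hand, made for the assembly NfurGRZ-RIMD1, lists no Ensembl IDs, and 0 of the 25475 IDs matched it. The 41 gene lists fixed before the data were examined (mevalonate and sterol synthesis, osteoclast and osteoblast genes, stress, metabolism, cell type markers and others), the panel of alendronate target genes and the tests of these lists could therefore not be matched to any row, and none was tested. The rule for named genes, also fixed in advance, asked for the genes with the smallest p per tissue among those at an adjusted p of 0.05 with a symbol or description. It named no gene. The only ID printed was chosen after its values were seen, because the count it belongs to is 1.

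In place of the lists, groups of genes were defined from the levels in these libraries, after the data had been seen. Levels were in CPM, which are counts scaled to a common library total after TMM factors adjusted each total. For these groups the factors came from all 42 libraries together. They ran from 0.364 in a liver library to 1.91 in a kidney library. Equal shares of counts therefore gave higher levels in liver than in spleen or kidney. A gene was called enriched in a tissue when its mean there was at least 5 CPM. That mean also had to be at least 10 times the mean in each of the other tissues, giving both arms equal weight. This gave 130 heart-enriched, 482 liver-enriched, 402 muscle-enriched, 44 spleen-enriched and 378 kidney-enriched genes. By the same limits 9 genes were shared by spleen and kidney against the other tissues, and 179 by heart and muscle. A further 2610 genes were evenly expressed, with a mean of at least 5 CPM in every tissue and less than a 2-fold range between tissues. These groups describe where a gene is expressed and name no pathway.

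Each tissue was tested on its own with edgeR 4.0.16 in R 4.3.3, using filterByExpr, TMM scaling and the quasi-likelihood F test with robust settings, with treatment as the only term. P-values were two-sided and adjusted by the Benjamini-Hochberg method over the genes of that tissue, with a threshold of 0.05 and no limit on the fold. Standard errors and 95% confidence intervals of log2 fold changes came from the same fits. The difference in treatment effect between tissues was tested with all treatment-by-tissue terms together over the 42 libraries. Gene group scores are the mean log2 CPM of the members in a library (prior count 2), compared by two-sided exact permutation tests and adjusted over 38 tests. Camera from limma 3.58.1 was run on the same groups with a preset and with an estimated correlation between genes. Overlaps between tissues were tested with one-sided Fisher's exact tests.

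Likeness between libraries of 1 fish was measured on log2 CPM after subtracting, within each tissue, the mean of the arm. The deviations were correlated across genes between tissues, and the fish were permuted within arm and tissue 100000 times. Genes are not independent replicates, so the test rests on the fish. Shares of counts in a library have 95% Wilson intervals no wider than 0.0208 percentage points to either side, over 336 shares. The reads carry no molecular identifiers, so these intervals cover counting error only. Replicate libraries were compared before use. No pair of libraries held identical values, and the smallest chi-square per degree of freedom among 72 replicate pairs was 26.7, so each library counted once.

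The fits were tested on simulated counts with the means, library sizes and dispersions of these libraries and 200 changed genes among those at 5 CPM or more. Of 100 genes changed 2-fold, the percentage recovered was 50 in heart, 31 in liver, 52 in muscle, 3 in spleen and 0 in kidney. Of 100 genes changed 4-fold it was 96, 95, 96, 62 and 24, in that order. In simulated data for all tissues together, the changed genes were drawn from those at 5 CPM or more in every tissue. Of those changed 4-fold in muscle only, 88% were called by the interaction test. No likeness between libraries of 1 fish was simulated. Genes were drawn independently of each other, so structure that many genes share between libraries was absent. With fewer than 200 changed genes, a smaller percentage could pass the adjustment. The percentages recovered need not hold for the real libraries.

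Alternatives fixed before the data were examined were DESeq2-type size factors, scaling without the 10 most abundant genes, no filter, a filter at 5 CPM, DESeq2 1.42.0, limma-voom with sample weights, settings without robust estimation, all libraries in one fit, a replicate block and leaving out each library in turn. After the data had been seen, fits without the liver-enriched genes in spleen, without 2 spleen libraries and with 1 surrogate variable (sva 3.50.0) were added, as were a 5-fold limit and other scalings for the gene groups. Splits of the libraries into groups of the same sizes were refitted, the real one included, all 56 in spleen, 100 in each of heart, liver and muscle, and 60 or 30 splits of the 9 fish for tests over several tissues. Kidney, with 2 placebo libraries, was left out of this step.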

Results

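The data are read counts from heart, liver, caudal fin muscle, spleen and kidney of female killifish. Treatment with 10 µM alendronate in the tank water began at 16 weeks of age and lasted 3 weeks, and all fish were 19 weeks old at sampling and kept at 28 °C. The series title places the work in a study of survival and bone in this model of fast ageing, and the comparison asks how the drug affected gene expression outside bone. Each tissue had 5 alendronate libraries. Heart, liver and muscle had 4 placebo libraries, spleen had 3 and kidney had 2. Total counts per library ran from 22497686 to 27422766 in heart, from 22285977 to 33890627 in liver, from 22171430 to 35717250 in muscle, from 20898321 to 27004620 in spleen and from 20485992 to 31067070 in kidney.

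The libraries grouped by tissue. All 42 libraries correlated best with another library of their own tissue, over 13178 genes. The median Pearson r across genes was 0.944 within tissues and 0.547 between them, and the lowest within-tissue value, 0.797, came from spleen. Genes enriched in liver supplied 66.4% of liver counts, and those enriched in muscle supplied 42.7% of muscle counts. Heart-enriched genes made up 7.81% of heart counts, kidney-enriched genes 3.96% of kidney counts and spleen-enriched genes 0.942% of spleen counts. In liver the 10 most abundant genes of a library took between 38.2% and 57.4% of its counts.

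In muscle, 1 gene was lower with alendronate and 0 were higher among the 15610 genes tested with edgeR. ENSNFUG00015020294 stood at 11.1 ± 4.42 CPM (SD, n = 5) with alendronate and at 67.2 ± 22.3 CPM (SD, n = 4) with placebo. All 5 treated libraries, from 6.25 to 16.7 CPM, lay below all 4 placebo libraries, from 44.9 to 96.6 CPM. The fitted log2 change was -2.59 with a standard error of 0.31 and an adjusted p of 0.0419 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, which is 6.04-fold lower with a 95% interval from 3.79 to 9.61. The gene belongs to the muscle-enriched group, and its mean in each arm of the other tissues was at most 0.242 CPM. The direction was the same in every alternative run, but the adjusted p rose above 0.05 without a filter (0.0769). It also did so with the replicate block (0.862), although the same number in both arms marks different fish. In the 9 fits that left out 1 muscle library it ran from 0.0257 to 0.443 and was above 0.05 in 8. Of these fits, only the one without alendronate fish 4 kept it under 0.05.

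**Figure D1:**
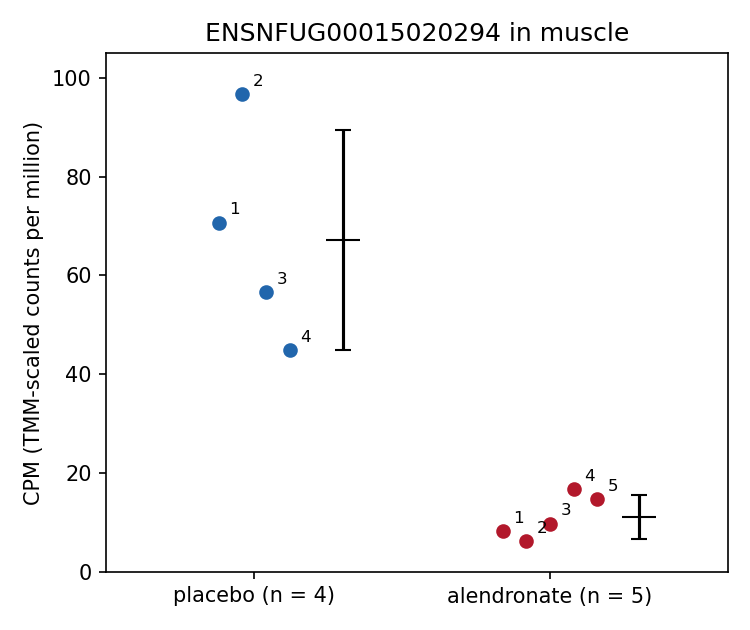
CPM of ENSNFUG00015020294 in each muscle library, scaled by TMM within muscle, by arm. Points are libraries with the fish number beside them, and bars show the mean and SD. The 5 alendronate libraries sit between 6.25 and 16.7 CPM and the 4 placebo libraries between 44.9 and 96.6 CPM.

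No gene group passed the exact permutation test in muscle, where 1 group on its own could not have passed after adjustment, however clear its difference. The muscle-enriched genes had a mean score of 6.21 ± 0.09 log2 CPM (SD, n = 5) with alendronate and 6.25 ± 0.07 (SD, n = 4) with placebo, a difference of -0.04 (exact permutation p = 0.556, adjusted p = 0.973), which ran from -0.06 to -0.004 when leaving out each library. The evenly expressed genes differed by 0.06 (exact permutation p = 0.0714, adjusted p = 0.724). Of the 72 heart-enriched genes tested in muscle, 51 had a fitted change below 0, and the scores were 0.98 ± 0.13 (SD, n = 5) with alendronate and 1.15 ± 0.08 (SD, n = 4) with placebo, a difference of -0.17 (exact permutation p = 0.0635, adjusted p = 0.724). The kidney-enriched genes differed by -0.51 (exact permutation p = 0.278, adjusted p = 0.776), with 50 of 57 below 0. This difference was -0.25 without placebo fish 3 and -0.94 without placebo fish 4, and these genes made up 0.0193% of counts in placebo fish 1 and 0.0256% in placebo fish 3, against 0.00586% to 0.0103% in the other 7 libraries. At an unadjusted p under 0.05 there were 1157 muscle genes, 511 higher and 646 lower, where 780.5 would be expected by chance. DESeq2 called 2 genes in muscle, both lower, and limma-voom 1. For 77.9% of muscle genes at 1 CPM or more, the 95% interval of the fold change lay within 2-fold in both directions.

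In heart, 0 of 15975 genes passed the threshold in edgeR, and the smallest adjusted p was 0.990. There were 419 genes at an unadjusted p under 0.05, where 798.75 would be expected, and both DESeq2 and limma-voom called 0. The 419 became 239 without placebo fish 2 and 814 without alendronate fish 5. Heart-enriched genes scored 6.62 ± 0.15 log2 CPM (SD, n = 5) with alendronate and 6.69 ± 0.13 (SD, n = 4) with placebo, a difference of -0.08 (exact permutation p = 0.444, adjusted p = 0.938), or from -0.13 to -0.03 when leaving out each library. The interval of the fold change lay within 2-fold for 80.9% of heart genes at 1 CPM or more, the highest percentage of the 5 tissues.

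In liver, 0 of 15167 genes passed in edgeR, with a smallest adjusted p of 0.914. At an unadjusted p under 0.05 there were 663 genes, 333 higher and 330 lower, against 758.35 expected. That number was 258 without placebo fish 1, 338 without placebo fish 3 and 1894 without placebo fish 4, each with 0 calls. DESeq2 called 1 gene, lower with alendronate, and limma-voom 0. The liver-enriched genes differed by -0.03 log2 CPM between arms (exact permutation p = 0.873, adjusted p = 1), at 6.21 ± 0.20 (SD, n = 5) with alendronate and 6.24 ± 0.08 (SD, n = 4) with placebo, and from -0.07 to 0.05 when leaving out each library. Of the 481 tested, 285 had a fitted change below 0. Their share of liver counts averaged 64.1% (SD 4.28, from 57.2% to 67.4%) with alendronate and 69.3% (SD 2.86, from 65.1% to 71.5%) with placebo. This difference in share was not tested. The kidney-enriched genes in liver had the smallest exact p of the 38 group comparisons. They scored -0.11 ± 0.20 (SD, n = 5) with alendronate and -0.45 ± 0.19 (SD, n = 4) with placebo, a difference of 0.33 (exact permutation p = 0.0556, adjusted p = 0.724) with 63 of 87 above 0, and from 0.25 to 0.43 when leaving out each library. In liver the heart-enriched, muscle-enriched, spleen-enriched and heart-and-muscle-shared genes also scored higher with alendronate, by 0.26 to 0.39 (exact permutation p from 0.183 to 0.254). These differences moved by over 1.5 times when leaving out single libraries. Heart-enriched genes differed by 0.19 without alendronate fish 2 and 0.21 without placebo fish 2, muscle-enriched genes by 0.14 without alendronate fish 2 and 0.40 without alendronate fish 3, spleen-enriched genes by 0.13 without placebo fish 1 and 0.26 without placebo fish 2, and heart-and-muscle-shared genes by 0.24 without alendronate fish 2 and 0.23 without placebo fish 1. The interval lay within 2-fold for 70.1% of liver genes at 1 CPM or more. Fitting all libraries together gave 3 genes in liver, 1 higher and 2 lower.

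In spleen, 0 of 17545 genes passed in edgeR, with a smallest adjusted p of 1.0. There were 285 genes at an unadjusted p under 0.05, 70 higher and 215 lower, against 877.25 expected. It was 436 without alendronate fish 1, 456 without alendronate fish 2 and 453 without placebo fish 2. DESeq2 called 10 genes, all lower with alendronate, and limma-voom 0. Counts from liver-enriched genes were uneven between spleen libraries. They made up 9.77% of the counts in alendronate fish 1 (95% Wilson interval from 9.75% to 9.78%) and 6.37% in alendronate fish 3 (from 6.36% to 6.38%), and between 0.474% and 2.25% in each of the other 6 spleen libraries. Of the 436 liver-enriched genes tested in spleen, 423 had a fitted change above 0, yet their scores, 2.60 ± 1.63 log2 CPM (SD, n = 5) and 1.70 ± 0.48 (SD, n = 3), differed by 0.91 (exact permutation p = 0.375, adjusted p = 0.905), and by 0.36 without alendronate fish 1 and 1.41 without alendronate fish 2. Spleen-enriched genes scored 6.03 ± 0.45 (SD, n = 5) with alendronate and 6.02 ± 0.30 (SD, n = 3) with placebo (exact permutation p = 1), and their difference ran from -0.12 without placebo fish 4 to 0.18 without alendronate fish 1. Without the spleen libraries of alendronate fish 1 and 3, a choice made after seeing the data, edgeR again called 0 genes, and 1129 had an unadjusted p under 0.05.

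**Figure D2:**
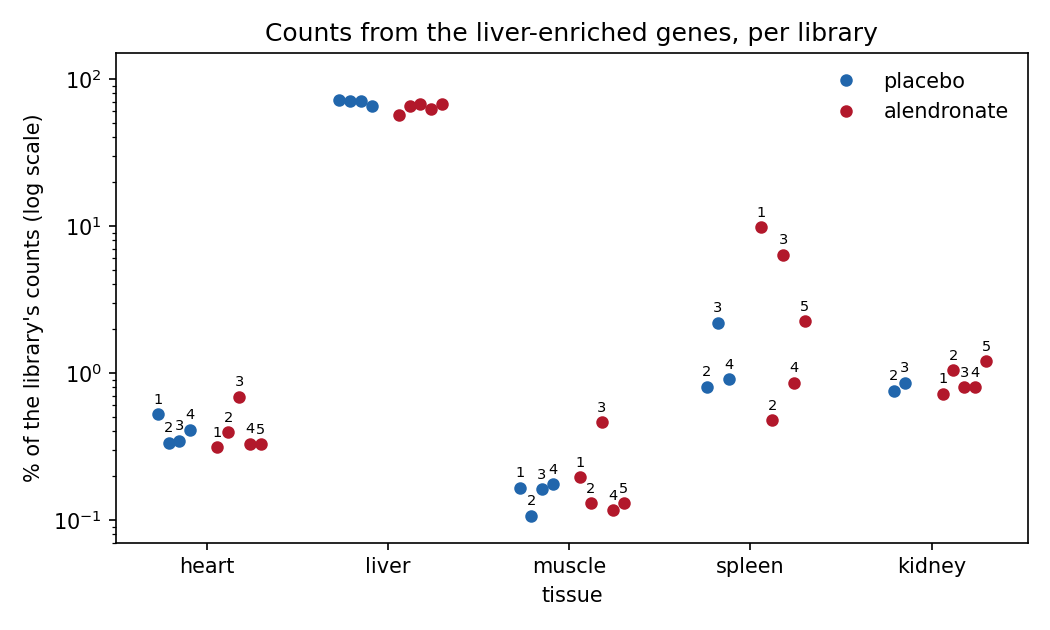
Percentage of each library's counts from the 482 liver-enriched genes, by tissue and arm, on a log axis. Each point is a library, with the fish number beside it outside liver. The spleen libraries of alendronate fish 1 and 3 stand at 9.77% and 6.37%, above the other 6 spleen libraries, and alendronate fish 3 is also highest in heart and muscle.

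In kidney, 0 of 19282 genes passed in edgeR, with a smallest adjusted p of 1.0. There were 328 genes at an unadjusted p under 0.05, 244 higher and 84 lower, against 964.1 expected. Leaving out alendronate fish 1 gave 991, alendronate fish 3 gave 186, placebo fish 2 gave 164 and placebo fish 3 gave 755. DESeq2 called 2 genes, 1 higher and 1 lower, and limma-voom 0. Kidney-enriched genes scored 4.58 ± 0.77 log2 CPM (SD, n = 5) with alendronate and 4.87 ± 0.86 (SD, n = 2) with placebo, while the median fitted change of the members was 0.08, of the opposite sign to the difference in scores (exact permutation p = 0.810, adjusted p = 1). That difference, -0.29, was -0.07 without alendronate fish 1, -0.91 without placebo fish 2 and 0.32 without placebo fish 3. Muscle-enriched genes made up 2.02% of kidney counts in alendronate fish 2, the highest share, and 0.170% in alendronate fish 1, the lowest. With 2 placebo libraries the exact test cannot give a p below 0.0476, and the interval of the fold change lay within 2-fold for 54.6% of kidney genes at 1 CPM or more.

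Over all tissues, 0 of 38 gene group comparisons passed by the exact permutation test, and the smallest adjusted p was 0.724. The exact p cannot fall below 0.00794 in heart, liver and muscle, 0.0179 in spleen and 0.0476 in kidney. A single group at that limit would not pass after adjustment over 38 tests. The absence of calls therefore cannot exclude a shift of 1 or a few groups. Camera with a preset correlation called 19 of the 38, and none held with an estimated correlation, where the smallest adjusted p was 0.673. The 9 genes shared by spleen and kidney had the largest negative differences in score of the groups tested in spleen and in kidney. They differed by -0.89 log2 CPM in spleen (exact permutation p = 0.0893, adjusted p = 0.724), by -0.62 in kidney (exact permutation p = 0.0952, adjusted p = 0.724) and by -0.77 in heart (exact permutation p = 0.254, adjusted p = 0.776). Their scores in spleen were 4.99 ± 0.74 (SD, n = 5) with alendronate and 5.88 ± 0.24 (SD, n = 3) with placebo. The spleen difference was -0.59 without alendronate fish 1, and the heart difference was -0.47 without alendronate fish 2 and -0.45 without placebo fish 4. With the limit lowered to 5-fold, the group grew to 138 genes and the differences were -0.43 in spleen, -0.12 in kidney, -0.25 in heart, -0.47 in muscle and 0.51 in liver.

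The effect of alendronate was not found to differ between tissues for any gene. The interaction test in edgeR called 0 of 20892 genes, with a smallest adjusted p of 0.171 and 846 genes at an unadjusted p under 0.05, against 1044.6 expected. The 846 became 543 without placebo fish 1 and 1505 without placebo fish 4. With fish as a block it also called 0, and DESeq2 was not run for this test. No gene was called by edgeR in more than 1 tissue. At an unadjusted p under 0.01 in both tissues of a pair, 11 pairings of a gene with 2 tissues went in one direction and 1 in opposite directions, where 1.65 in one direction would be expected of independent lists. One-sided Fisher's exact tests on these overlaps gave an adjusted p of 0.0379 each for heart with muscle, heart with spleen and muscle with spleen. No other pair of tissues passed. The gene lists are not independent, since the tissues came from the same fish. These p-values therefore cannot tell treatment from likeness between libraries of 1 fish.

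Libraries of the same fish resembled each other across tissues. After removal of the arm means, the mean Pearson r across genes between 2 tissues of 1 fish ranged from 0.20 to 0.36 over the 10 pairs of tissues, and that between different fish from -0.04 to -0.02. Deviations from an arm mean sum to 0, so a positive same-fish r pulls the different-fish mean below 0. The permutations used the same deviations. The excess of same-fish over different-fish correlation averaged 0.324 (permutation p = 1e-05, the smallest that 100000 permutations can give).

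**Figure D3:**
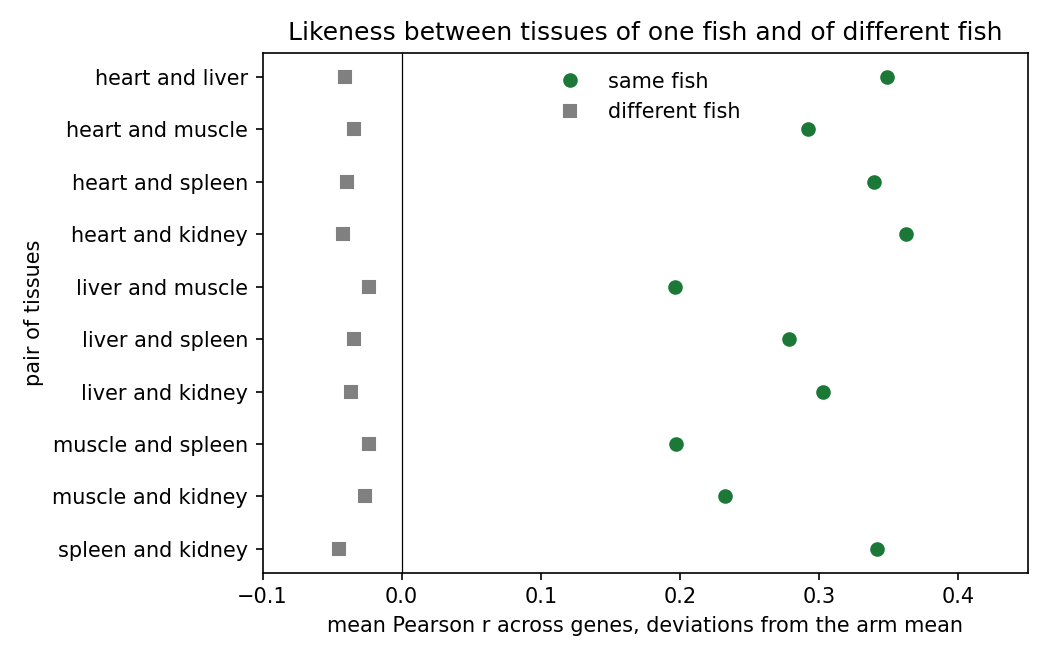
Mean Pearson r across genes between the deviations of 2 libraries from their arm means, for each pair of tissues. Circles are libraries of the same fish and squares libraries of different fish. Same-fish values lie between 0.20 and 0.36 and different-fish values between -0.04 and -0.02. Subtracting the arm means pulls the different-fish values below 0 where same-fish values are positive.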

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

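The tests on the order of serial numbers and on spleen shares between arms were chosen after the result was seen. The bounds for the tests on carry-over, depth and liver tissue were set before their results. Over 82 comparisons within groups of 4 or 5 libraries, 18 had a highest or lowest library far from the rest by Dixon's gap test. For independent, normally distributed values chance gives about 1 in 20, or 4.1. That number need not hold here, since many values are small percentages and shares of 1 library depend on each other. Libraries of 1 fish also resemble each other. Of the 18, 9 belonged to placebo fish 4 and 5 to alendronate fish 1, and those of 1 fish are not separate events.

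Placebo fish 4 stood apart in heart, liver and muscle. In its heart, spleen-enriched genes made up 0.0349% of counts (next library 0.0159%), kidney-enriched genes 0.0283% and the 10 most abundant genes 11.6%, the lowest of its group. In its liver, the 10 most abundant genes took 46.8% (next library 56.4%), heart-enriched genes 0.0150%, spleen-enriched genes 0.00866%, spleen-and-kidney-shared genes 0.000821% and heart-and-muscle-shared genes 0.009997%. In its muscle, evenly expressed genes made up 6.90% of counts. In alendronate fish 1, spleen-enriched genes were at 0.0312% in heart and 0.0134% in liver, heart-enriched genes at 0.0199% in liver, spleen-and-kidney-shared genes at 0.000466% in muscle and evenly expressed genes at 12.0% in spleen. In alendronate fish 3, liver-enriched genes made up 0.689% of heart counts and 0.461% of muscle counts. In alendronate fish 4, heart-and-muscle-shared genes reached 11.6% of muscle counts, and placebo fish 2 had the deepest heart library of its group, at 25.6 M (mega) counts.

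Libraries of 1 fish resembled each other across tissues. Carry-over of reads between libraries of a fish would fade on the 2610 evenly expressed genes. A small carry-over moves their levels little where tissues hold them in like shares of counts. These genes made up 12.1% of heart, 14.5% of spleen and 14.1% of kidney counts, but 3.75% of liver and 5.89% of muscle counts. Carry-over into liver or muscle could therefore move them. The excess on these genes averaged 0.326 (permutation p = 1e-05, the smallest that 100000 permutations can give). It was 0.383 between heart and spleen, 0.487 between heart and kidney and 0.494 between spleen and kidney. Against all genes, it fell from 0.220 to 0.126 between liver and muscle and from 0.221 to 0.101 between muscle and spleen. Carry-over is argued against as the whole of the likeness between heart, spleen and kidney. In the pairs with liver or muscle a part of it is not excluded. Depth is argued against as well, because thinning every library to the smallest total left an excess of 0.318, against 0.324 before. The serial numbers of the libraries form an unbroken run for 9 of 9 fish, so differences between fish cannot be told apart from handling each fish as a batch. All alendronate libraries precede all placebo libraries in these numbers, so treatment cannot be told apart from this order either. Biological differences between fish stay open and untested.

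The high share of liver-enriched genes in the spleen libraries of alendronate fish 1 and 3 may come from liver tissue in the spleen samples. Reads carried over from the liver library of the same fish would give a common fraction of the liver level too. The test below cannot tell these sources apart. Alendronate fish 3 also had the highest share of liver-enriched genes in heart (0.689%) and in muscle (0.461%). Among liver-enriched genes at 50 CPM or more in the liver of the same fish, the excess over the other spleen libraries lay within 2-fold of a common fraction of the liver level for 95.13% of genes in fish 1 and 81.53% in fish 3, against a bound of 80% set before. That fraction, taken between TMM-scaled levels, had a median of 7.16% in fish 1 and 1.59% in fish 3. For the 10 genes most abundant in liver it ran from 5.97% to 9.96% and from 1.46% to 3.35%. It is not the share of liver reads in the spleen library, which would be larger. The TMM factors were 1.44 and 1.81 in the spleen libraries of fish 1 and 3, against 0.687 and 0.474 in their liver libraries. The minimum of 50 CPM was not part of the bound, and with 10 CPM the value for fish 3 was 76.6%, below it. A rise with treatment is not decided either way. The share averaged 3.94% with alendronate and 1.30% with placebo (exact permutation p = 0.3393, n = 5 and n = 3), and 3 of the 5 alendronate libraries lie above every placebo library.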

How the results depend on the processing

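Counts of genes past the threshold stayed within 1.5 times the reported count in 78 of 94 alternatives for the tissues and in all 14 for the interaction. With DESeq2 the count was 1 in liver, 2 in muscle, 10 in spleen and 2 in kidney, and with all libraries in one fit it was 3 in liver. In muscle it was 0 without a filter, where more genes are tested, and from 0 to 1 when leaving out each library. Counting overlaps at an unadjusted p under 0.01 gave 11 in place of 0. Apart from the cases whose construction is given, the cause was not tested. The muscle gene kept its direction in 19 alternatives, from a log2 change of -2.79 to -2.36, and lost its call in 10 of them, with adjusted p from 5.9e-13 to 0.862. Counts at an unadjusted p under 0.05 moved by over 1.5 times in 32 of 94 alternatives. Of 394 alternatives for the gene group differences, 344 kept the sign. Fits chosen after seeing the data (1 surrogate variable, spleen without liver-enriched genes or without fish 1 and 3) changed no count of calls, while the genes at an unadjusted p under 0.05 went with 1 surrogate variable from 285 to 731 in spleen, from 663 to 319 in liver and from 328 to 706 in kidney, and to 1129 in spleen without fish 1 and 3.

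Fish with the same number in both arms are different fish, and their deviations went together in some pairs only (r over 0.1 in 1 of 4 pairs in heart and in liver, 2 of 4 in muscle, 2 of 3 in spleen and 1 of 2 in kidney). Number 2 was above 0 in every tissue (0.04 to 0.44), as was number 3 (0.05 to 0.20), while 1 and 4 were below 0 wherever both arms had them. Few fish were closest to their own number (0 of 4 in heart and liver, 1 of 4 in muscle, 0 of 3 in spleen, 1 of 2 in kidney). With the replicate block, muscle had 0 calls and kidney 3, and no other count of calls changed, while counts at an unadjusted p under 0.05 were 932 in heart, 431 in liver, 823 in muscle, 336 in spleen and 1571 in kidney. The tests of the 41 gene lists and their alternatives (estimated correlation, fry, other scaling, replicate block, leaving out libraries) were not run, since no ID could be matched. Depth was at least 20485992 counts in every library.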

Other observations

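Tests in this part were fixed before their results except those on the fish mean of the genes shared by spleen and kidney, on unscaled counts, on muscle-enriched genes and on shuffled deviations, which were chosen after the result was seen. The scores of those 9 genes were lower with alendronate in heart, spleen and kidney, though not past the threshold in any of them. As a deviation from the midpoint of the arms in each tissue, averaged over the tissues sampled in each fish (placebo fish 1 has no spleen or kidney library and placebo fish 4 no kidney library), the score was -0.36 ± 0.32 log2 CPM (SD, n = 5) with alendronate and 0.35 ± 0.34 (SD, n = 4) with placebo, a difference of -0.71 (two-sided exact permutation p = 0.0238, not adjusted for the choice of this group among 8). In the wider group of 138 genes the difference was -0.18 (exact permutation p = 0.524). The 0.0238 rests in part on the lower scores already seen in heart, spleen and kidney and so adds no support of its own. It averages in liver and muscle, where too few of the 9 genes passed the count filter to be tested with all libraries. Enough of them passed in some fits without 1 placebo library. Those that passed differed by -0.14 in liver and -1.28 in muscle without placebo fish 3, and by -0.10 in liver without placebo fish 2. The 9 genes together made up only 0.00013% to 0.00063% of counts in a muscle library, near the floor. The wider group was higher in liver by 0.51 and lower in muscle by 0.47. A shift in every tissue of a treated fish stays undecided. With no gene names, what the group does could not be asked.

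In the fits of each tissue on its own, with treatment as the only term, the muscle gene ENSNFUG00015020294 is the only gene edgeR called. Scaling is argued against as its source, since counts before any scaling were 6.222-fold lower on average, from 164 to 445 with alendronate and from 1325 to 3302 with placebo, while library sizes differed by at most 1.63-fold. The other scalings moved almost no gene (95% of muscle genes by at most 0.00457 in log2) and so test nothing. A single library is argued against, since the fold was at least 5.14 without any of the 9. A lower share of muscle in the treated samples is argued against too, since the muscle-enriched genes differed by only -0.0358 in mean log2 score (standard error 0.0566, from -0.0624 to -0.00371 when leaving out each library), where the gene itself fell by 2.59. As a share of muscle counts these genes were at 41.5% (SD 0.72, n = 5) with alendronate and 44.2% (SD 3.09, n = 4) with placebo. That is lower, but far short of the fold of the gene. Another mix of cells or tissues that keeps the share of muscle stays open. The 100 genes that follow the gene most closely within the arms had a median log2 change of 0.103, above the bound of -0.5 set before, but that bound assumed that they follow it beyond chance, and 44.9% of 1000 shuffles of its deviations gave at least as many genes as close. Chance is not excluded for the call, as 7 of 100 splits of the muscle libraries, the real one included, gave at least 1 gene, the highest of the others 6. Chance is not excluded for the 1157 muscle genes at an unadjusted p under 0.05 either, since 10 of 100 splits, the real one included, gave as many, up to 1528. Whether the drug lowered this gene or fish of one arm differ for another reason, such as their tank or the order of the libraries, stays open.

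With a real count of 0 calls every split gives at least as many, 100 of 100 in heart and in liver, 56 of 56 in spleen and 60 of 60 over the fish for the interaction, so these comparisons say nothing about chance. Most splits called 0 genes, 96 in heart, 95 in liver, 93 in muscle and 53 in spleen. A few called far more. The highest called 981 genes in liver and set alendronate fish 3 with placebo fish 1, 2 and 3 against the rest. In spleen the highest called 1831 and set alendronate fish 1 and 3 with placebo fish 4 against the rest. In heart the highest was 37 and in the interaction 243. That liver split differs from the real grouping by the exchange of alendronate fish 3 and placebo fish 4, so 7 of the 9 fish keep their side. These few splits point to a structure of the samples beyond the real grouping, and whether it is unrelated to treatment was not tested.

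A shift common to the 5 tissues was tested with limma-voom and fish as a random block. It called 0 of 20892 genes, with 375 at an unadjusted p under 0.05 against 1044.6 expected, while 30 of 30 splits of the fish gave at least 0, as any split must, and the highest 1350. In simulated data for this test on 20892 genes, with no likeness between libraries of a fish built in, 99% of genes changed 2-fold in every tissue were called. Of the 159 calls there, 60 were of other genes, 8 of them unchanged and the rest changed in muscle only. The 11 pairings at an unadjusted p under 0.01 in 2 tissues are not beyond chance, since 41 of 60 splits of the fish gave as many, with a median of 19 and a highest of 2039.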
